A study of Mus musculus with 18 samples.

How the data were processed

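RNA was measured in 18 mice, 1 library per mouse, from cells of the epidermal side of dorsal skin. Per the labels' protocols, shaved skin in telogen, the resting phase of the hair cycle, was held overnight in trypsin, the epidermis was scraped from the dermis and passed through a mesh, and poly(A) RNA was sequenced by a commercial provider. The deposited table holds raw counts of reads per gene, 21011 genes by 18 columns, with no normalization applied. The authors' steps before deposit, per the submitters' processing notes, used STAR, HTSeq and DESeq2 with the mouse build mm10, and no versions are stated. Which of these tools made which value, and whether strand was used in counting, is not given in the sources used here, so reads of overlapping, antisense or near-identical genes may have been split or lost. This applies to the Sprr2a, Gsdmc, Stfa and Skint families and to mitochondrial genes with nuclear copies.

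All columns were matched to a mouse by name. Of the rows, 15418 carry a symbol found in GENCODE M21, the annotation on GRCm38 (the same assembly as mm10) from which the coordinates were taken. Total counts ran from 8076316 to 21216169 per library. The 2 deepest libraries, KR control 4 and KN1 control 1, each merge reads that the labels say came from 1 mouse on 2 sequencing occasions, and the table holds them as 1 column each. The labels also give KR control 6, LR control 5 and KN1 control 7 a second name that, like those of the repeat runs, ends in 2, without stating an occasion. These 3 controls are called second-named here.

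Group means of each mutant were compared with those of its own controls, which share its batch. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM factors, robust dispersion estimation and 6 group means. Every deposited row already had a total count of at least 18, and filterByExpr kept 16517 genes. Groups of 2 controls took their spread from all 18 mice, and the common biological coefficient of variation was 0.225. Benjamini-Hochberg adjustment was applied at 0.05 and all tests were two-sided. Standard errors of log2 fold changes were taken from the F statistic. Levels are CPM (counts scaled to library size) computed from the deposited counts and TMM factors, given as mean ± SD over mice, and mean log2 CPM values used a prior count of 2. Differences between mutants were tested as differences of contrasts in the same fit.

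For gene lists, camera (limma 3.58.1) was run with a preset correlation of 0.01 between genes over the 32 of 35 lists with at least 4 tested genes, and then with a correlation estimated per list. No list passed with an estimated correlation in any of the 3 comparisons. Lists, tests and the rule for named genes were fixed before the data were examined. The rule named Rbpj, Notch1, Lrig1 and Krt14. It added up to 7 higher and 7 lower genes with the largest fold change among those past the threshold, with at least 5 CPM in the higher group, every mutant mouse beyond every control, and an ordinary gene symbol. It also took up to 4 members with the smallest adjusted p from each list described, and up to 5 genes per direction of each difference test. Genes named outside it are said to be so, and some results that the rule selects are not reported here. A gene with no count in a group was given a bound from 3 counts over the group, which covers counting error only.

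The fit was tested on simulated counts for 16517 genes drawn with the means and depths of these libraries. The changed genes were drawn from those with a mean CPM of at least 1, so recovery of genes below that level was not measured. Of 100 genes changed by 2-fold, 41% were recovered in KR, 55% in LR and 38% in KN1. Of 100 genes changed by 4-fold, 91%, 91% and 88% were recovered. False calls made up 6.38%, 5.19% and 3.08% of the calls. The genes were drawn independently, each from 1 mean, with no shift shared by the genes of a mouse or cohort. False calls from such shifts are not in these rates. The alternatives were DESeq2 1.42.0, RLE factors, no filter, a mean CPM of at least 1, each cohort fitted alone, all 7 controls pooled, a replicate block in LR, fry, and each mouse left out. After the data were seen, a covariate for the second-named share of each library, a covariate for sex and the omission of second-named controls were added. The share was 0 in all mutants and 0.5 or 1 in all KR and KN1 controls. For KR and KN1 the covariate thus extends beyond the shares of their controls. Omitting the second-named controls left 1 control in KR and 1 in KN1, both merged libraries. The 2 runs of a merged mouse were not analysed here one by one.

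Each sample is a separate mouse, and p-values measure the spread between these mice. Libraries of 1 group differed by more than sampling noise: the chi-square per degree of freedom between pairs was at least 6.41, so no library was counted as a repeat of another.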

Results

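The series asked how loss of Notch signalling in different parts of the epidermis alters gene expression in resting mouse skin, including its sebaceous glands. Notch1 is a receptor, and Rbpj is the DNA-binding protein through which Notch receptors act on their target genes. Tamoxifen was given at 8 weeks of age to switch on Cre recombinase, and skin was taken 10 weeks later. In KR mice (n = 4), K14-CreERT, active in the basal layer, deleted Rbpj. In LR mice (n = 3), Lrig1-CreERT2, driven from a gene of upper hair follicle stem cells, deleted Rbpj. In KN1 mice (n = 4), a K14-CreERT deleted Notch1; the labels write it K14-CreERT1 for these mice and K14-CreERT for KR, and the names are taken here as 1 driver. Each mutant had controls of its own batch: 2 for KR, 3 for LR and 2 for KN1. Total counts were 8076316 to 9562955 in KR and 11236817 to 20260259 in its controls. They were 8541208 to 11239648 in LR and 8299785 to 11056572 in its controls, and 8103155 to 9213875 in KN1 and 10926731 to 21216169 in its controls.

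The deleted genes were examined first, and adjusted p-values of genes here are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and those of lists from camera. Notch1 (chromosome 2, 26457903 to 26516663, minus strand, GRCm38/mm10, protein coding) fell in KN1, with 112 ± 31.2 CPM (SD, n = 4) against 212 ± 56.2 CPM (n = 2) in the controls, a log2 fold change of -0.91 ± 0.19 (SE, adjusted p = 0.0251). It was level in KR, with 349 ± 29.9 against 334 ± 10.9 CPM, and in LR, with 369 ± 35.3 against 380 ± 33.4 CPM. Rbpj (chromosome 5, 53466152 to 53657362, plus strand) did not pass the test in any mutant. Its log2 fold change was -0.47 ± 0.17 in KR (adjusted p = 0.135), -0.66 ± 0.17 in LR (adjusted p = 0.0659) and -0.34 ± 0.18 in KN1 (adjusted p = 0.31), where Rbpj was not the deleted gene. These are counts over whole genes, which do not resolve a deleted exon, so Rbpj does not check the labels of the KR and LR mice. Lrig1 did not pass in any mutant, and Krt14, the basal keratin whose promoter drives K14-CreERT, rose in KR only by this test: 10324 ± 1366 against 5832 ± 223 CPM, a log2 fold change of 0.82 ± 0.16 (adjusted p = 0.0211). Krt14 changed by 0.48 in LR (adjusted p = 0.116) and by 0.15 in KN1 (adjusted p = 0.644), and no difference between mutants in Krt14 passed.

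Genes that Notch signalling is known to switch on did not move as a list. The Notch target list had median log2 fold changes of -0.07 in KR, 0.03 in LR and 0.24 in KN1 (camera adjusted p = 0.548, 0.538 and 0.484). The list of 29 Notch pathway components had medians of -0.08, -0.02 and -0.06 (adjusted p = 0.982, 0.398 and 0.821), with Notch1 in KN1 as its 1 changed gene.

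**Figure D1:**
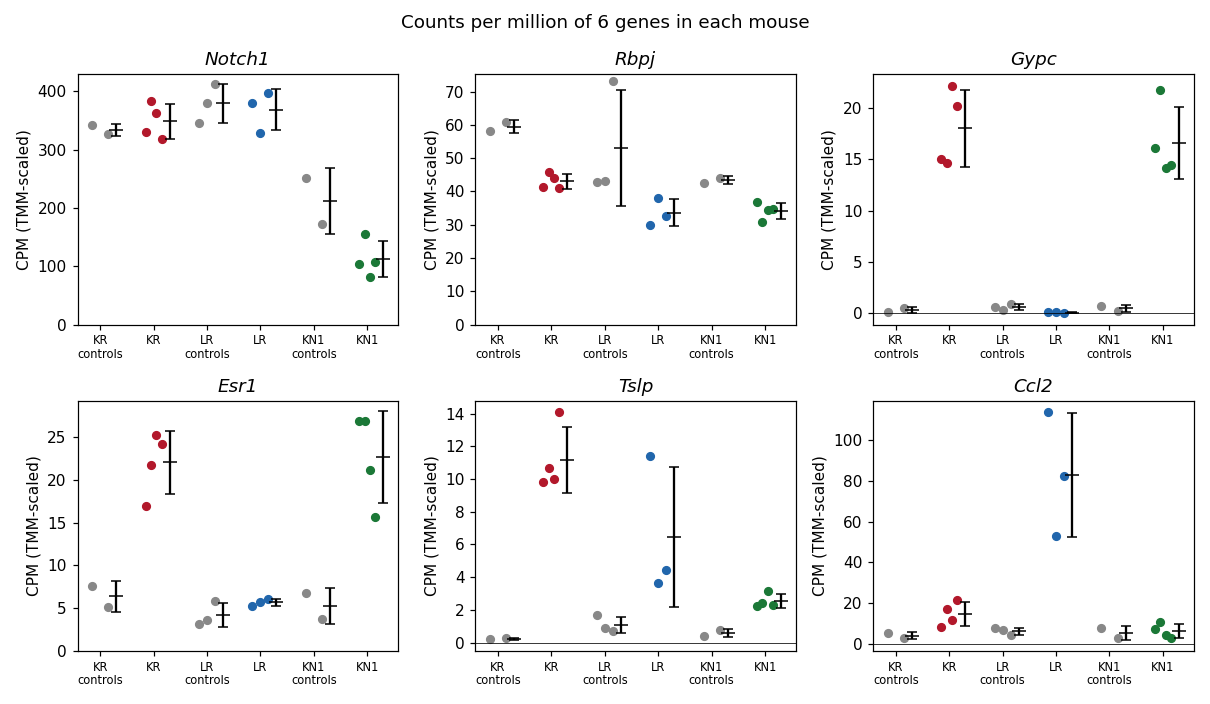
CPM of 6 genes in each mouse (points), with the mean and SD of each group (bars), for the 3 mutants and their own controls. Gypc lay between 14.1 and 22.2 CPM in the 8 KR and KN1 mice and at or below 0.894 CPM in the other 10, and Ccl2 was at 52.9 to 114 CPM in the LR mice and at or below 21.6 CPM in all others.

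In KR skin, where Rbpj was deleted from the basal layer, 264 of 16517 genes changed: 115 rose and 149 fell, 82 and 63 of them by at least 2-fold. The epithelial cytokine Tslp rose from 0.232 ± 0.0545 CPM in 2 controls to 11.2 ± 1.99 CPM in 4 mutants (log2 fold change 5.58 ± 0.58, adjusted p = 0.000128). The gut hormone gene Pyy rose from 38.9 ± 4.55 to 893 ± 330 CPM (4.52 ± 0.59, adjusted p = 0.0053). Gypc, known for its red cell membrane protein, rose from 0.319 to 18 CPM (6.02 ± 0.53, adjusted p = 2.02e-05). Gsdmc2 (4.43), the cornified envelope gene Sprr2a3 (4.15) and the protease inhibitor gene Serpina3n (3.97) were also among the largest rises.

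Among genes that fell in KR were Btc, which encodes the epidermal growth factor receptor ligand betacellulin (-2.41 ± 0.48, from 42.6 to 8.01 CPM, adjusted p = 0.0316), and Sebox (-2.15). The other 5 of the 7 named genes that fell were mitochondrial: mt-Atp6, mt-Co3, mt-Co2, mt-Nd3 and mt-Ts1, with log2 fold changes from -3.92 to -1.91. Counts on mitochondrial genes made up 2.52 ± 0.923% of the KR controls and 1.25 ± 0.327% of the KR libraries. The mitochondrial list was lower as a whole (6 of 15 fell, 14 adjusted over the list alone, adjusted p = 5.56e-14, and adjusted p = 0.485 with an estimated correlation). Its mean log2 CPM was 7.81 and 8.75 in KR controls 4 and 6, merged and second-named, against 5.92 to 6.70 in KR. The second-named LR control 5 had 8.12, and LR controls 2 and 3 had 5.90 each.

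Lists of keratinocyte states moved in KR. The list of suprabasal genes, expressed in the differentiating layers, was lower, with a median log2 fold change of -0.38 and 32 of 44 members negative (adjusted p = 6.16e-05, and adjusted p = 0.739 with an estimated correlation). Of its members 1 fell, the desmosomal cadherin Dsg1a (-1.40 ± 0.31, adjusted p = 0.0385), and 13 fell and 1 rose adjusted over the list alone. Dsc1 had -1.29 (adjusted p = 0.0598). The wound and stress list was higher, with a median of 0.81 over 30 members (adjusted p = 0.0222, and adjusted p = 0.739 with an estimated correlation). In it 3 genes rose over all genes, Sprr2a3, Sprr2a1 (3.20) and the neutrophil chemokine Cxcl1, and 9 rose and 2 fell adjusted over the list alone. Cxcl1 had 29 counts in the KR mice and 0 in the controls, which makes it at least 8.00-fold higher. The basal list did not pass (adjusted p = 0.0555, and adjusted p = 0.676 with an estimated correlation). Ifitm3 (1.27), Thbs1 (1.44) and Krt14 rose in it, and 5 of 19 rose adjusted over the list alone.

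Genes of antigen presentation were also higher in KR. All 7 genes of the MHC class II list had positive log2 fold changes, with a median of 0.80 (adjusted p = 2.18e-05, and adjusted p = 0.509 with an estimated correlation). H2-DMa rose (1.17 ± 0.25, adjusted p = 0.0344), 5 of 7 rose adjusted over the list alone, and H2-Eb1 and H2-Ab1 had 1.06 and 0.98 (adjusted p = 0.056 and 0.0699). The list of Langerhans cells, the antigen-presenting cells of the epidermis, was higher with a median of 0.77 (adjusted p = 0.000511, and adjusted p = 0.485 with an estimated correlation). In it Mfge8 rose (1.14), and 6 of 11 rose adjusted over the list alone. Sebocyte genes had a median of 0.56, with 32 of 38 positive and 0 changed either way (adjusted p = 0.137). Lists of endothelial cells and of macrophages and neutrophils had adjusted p = 0.121 each, and fibroblasts had 0.534.

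The KR count depended on which mice were used, in both directions. It was 1353 without LR control 5, which is outside this comparison, 809 with all 7 controls pooled and 651 without KR 4. Leaving out the 3 second-named controls or KR control 6 left KR control 4 as the only KR control. With a covariate for the second-named share of each library 12 genes were called, without the 3 second-named controls 32, and without KR control 6 alone 5. The wound and stress list did not pass with the covariate (median 0.75, adjusted p = 0.0994), without KR control 4 (0.71, adjusted p = 0.349) or without KR 3 (0.55, adjusted p = 0.0507), against a median of 0.81. With the covariate the mitochondrial median went from -1.64 to -0.43 (adjusted p = 0.000423, and adjusted p = 0.471 with an estimated correlation) and the suprabasal median from -0.38 to -0.84 (adjusted p = 3.62e-13, and adjusted p = 0.32 with an estimated correlation). The MHC class II (3.14e-06, and adjusted p = 0.32 with an estimated correlation) and Langerhans (2.67e-05, and adjusted p = 0.266 with an estimated correlation) lists passed with it. The MHC class II median went from 0.80 to 0.43 with the 3 second-named controls left out. The Langerhans median went from 0.77 to 0.48 without KR control 6 and to 1.25 without KR control 4.

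Some KR lists that did not pass in the first fit passed under these alternatives. The basal list passed with the covariate (median 0.30, adjusted p = 3.22e-05, and adjusted p = 0.266 with an estimated correlation). Cell cycle, with a median of 0.22 in the first fit (adjusted p = 0.121), had 0.67 with the covariate (adjusted p = 3.14e-06, and adjusted p = 0.471 with an estimated correlation). With the covariate, lists of other cell types passed too: endothelial cells (median 1.94, adjusted p = 0.000169), fibroblasts (0.0281) and melanocytes (0.0164). With an estimated correlation these had adjusted p = 0.266, 0.471 and 0.471. With the 3 controls left out the cell cycle median was 0.63 and the endothelial median 1.60. That fit drops KR control 6, which lay within the range of the KR mice on these lists and above KR control 4. Its mean log2 CPM for cell cycle was 4.96, against 4.21 in KR control 4 and 4.41 to 5.24 in KR. The melanocyte means were 3.08, 1.95 and 2.31 to 3.47, and the fibroblast means 3.35, 2.66 and 2.73 to 3.69. The endothelial means were 0.446, 0.0748 and -0.0638 to 1.70. Bulge stem cell genes passed with the covariate (median 0.43, adjusted p = 0.00131, and adjusted p = 0.471 with an estimated correlation). The hair matrix list, at 0.51 in the first fit (adjusted p = 0.667), was at 3.72 with the 3 controls left out (adjusted p = 0.0068, and adjusted p = 0.763 with an estimated correlation), 1 of them KR control 6, where hair matrix genes were high. Gypc and Tslp were called in all 16 alternatives.

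In LR skin, where Rbpj was deleted by Lrig1-CreERT2, 185 genes changed: 144 rose and 41 fell, 107 and 19 by at least 2-fold. The chemokine genes Ccl2 and Ccl1 were among the named genes that rose. Ccl2, which attracts monocytes, rose from 6.12 ± 1.79 CPM in 3 controls to 83 ± 30.4 CPM in 3 mutants (log2 fold change 3.77 ± 0.51, adjusted p = 0.00149), and Ccl1 from 0.176 to 6.95 CPM (5.22 ± 0.74, adjusted p = 0.0012). Stfa3, a stefin (cysteine protease inhibitor) gene, rose by 4.81, Tmem150c by 4.40, Bcl2a1d, of the anti-apoptotic Bcl2 family, by 4.12 and the sphingosine-1-phosphate receptor gene S1pr3 by 2.89.

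Among genes that fell in LR, the protein kinase C gene Prkcq (log2 fold change -2.23 ± 0.31, adjusted p = 0.0012) and the desmosomal cadherin Dsc2 (-1.69 ± 0.25, from 116 to 36.1 CPM, adjusted p = 0.00163) had the smallest adjusted p. Myoc (-1.82), Lurap1l (-1.81), Kcng4 (-1.73), Dpysl3 (-1.67) and the thrombomodulin gene Thbd (-1.47) were the others with the largest falls among genes at 5 CPM or more in the controls with no overlap between groups. Genes called in every one of 16 alternatives included Ccl1, Ccl2, Ifitm3, Prkcq, S1pr3, Tmem150c, Ceacam12 and RP24-138O17.3.

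The cholesterol synthesis and sebocyte lists were lower in LR, and fatty acid oxidation did not pass (median -0.22, adjusted p = 0.0629). Cholesterol synthesis genes had a median log2 fold change of -0.50 with 22 of 23 members negative (adjusted p = 3.29e-08, and adjusted p = 0.577 with an estimated correlation). None of them fell over all genes and 11 fell adjusted over the list alone. Stard4, a cholesterol carrier, had -0.78 (adjusted p = 0.0511) and Hmgcs1, an early enzyme of the pathway, -0.64 (adjusted p = 0.0714). Sebocyte genes had a median of -0.46 with 29 of 38 negative (adjusted p = 0.00491, and adjusted p = 0.662 with an estimated correlation). No sebocyte gene changed on either adjustment; Dgat2, a triglyceride synthesis enzyme, had -0.68 (adjusted p = 0.221) and the melanocortin receptor Mc5r -1.38 (adjusted p = 0.189). The sebocyte list did not pass without LR control 2 (median -0.35, adjusted p = 0.0648) or LR 1 (-0.25, adjusted p = 0.0745).

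Cell cycle genes were higher in LR as a list, with 39 of 40 positive and a median of 0.60 (adjusted p = 3.29e-08, and adjusted p = 0.577 with an estimated correlation). No member rose on either adjustment. The mitotic kinase genes Aurkb and Cdk1 had 1.16 (adjusted p = 0.14) and 0.91 (adjusted p = 0.168). The cell cycle median was 0.39 without LR 3 (camera adjusted p = 5.11e-05, and adjusted p = 0.631 with an estimated correlation). The wound and stress list was higher (median 1.06, 2 rose and 3 rose adjusted over the list alone, adjusted p = 0.00046, and adjusted p = 0.577 with an estimated correlation), with Stfa3 and Sprr2a3 (2.76) as its called members. The suprabasal list was lower (median -0.30, 33 of 44 negative, none changed, adjusted p = 0.00117, and adjusted p = 0.662 with an estimated correlation), and its member Dsg1a had -1.05 (adjusted p = 0.112). The suprabasal list did not pass without LR control 2 (median -0.19, adjusted p = 0.0979) or LR 3 (median -0.07, adjusted p = 0.574).

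Of the immune lists, 2 were higher and 1 was lower in LR. The MHC class II list was higher (median 0.63, 7 of 7 positive, adjusted p = 0.000194, and adjusted p = 0.577 with an estimated correlation), with 0 called over all genes and 4 adjusted over the list alone. The Langerhans list was higher (median 0.48, adjusted p = 0.0031, and adjusted p = 0.577 with an estimated correlation), with 0 and 2 called. The epidermal T cell list was lower (median -0.62, 20 of 24 negative, adjusted p = 0.00037, and adjusted p = 0.577 with an estimated correlation), with 0 and 6 called, and Tcrg-C1 had -1.33 (adjusted p = 0.091). The mitochondrial list was lower (median -0.85, none called, adjusted p = 0.00407, and adjusted p = 0.662 with an estimated correlation), and mitochondrial counts made up 2.26% of LR control 5 against 0.895% and 0.892% of LR controls 2 and 3. Without LR control 5 the T cell list (median -0.25, adjusted p = 0.0859) and the wound and stress list (median 0.78, adjusted p = 0.0535) no longer passed. The mitochondrial median turned from -0.85 to 0.10 without that control (adjusted p = 0.552). The mitochondrial list was also not called without LR 1 (median -0.73, adjusted p = 0.0584). Without LR control 5, 119 genes were called in place of 185. Leaving out LR control 3 or LR 3 gave 70 and 60 genes, and LR 1 118. With the covariate the bulge stem cell (median 0.47, adjusted p = 0.0287), basal (0.12, adjusted p = 0.0439) and melanocyte (0.86, adjusted p = 0.0494) lists passed in LR too (each adjusted p = 0.61 with an estimated correlation).

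**Figure D2:**
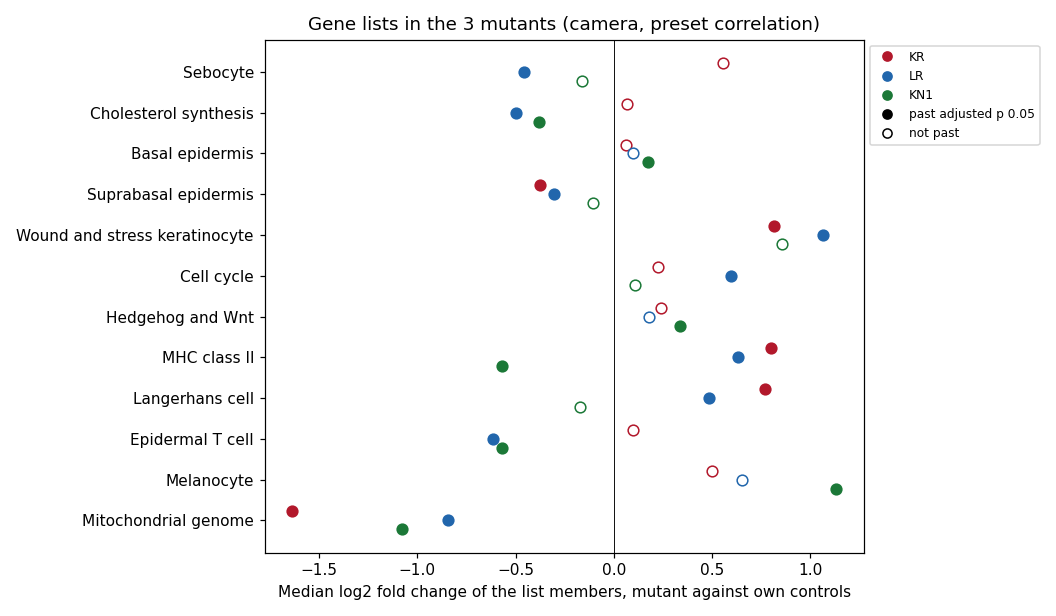
Median log2 fold change of the members of each gene list in KR, LR and KN1 against their own controls; filled points passed camera with a preset correlation at an adjusted p of 0.05 and open points did not. The hair matrix list, at 3.74 in KN1, lies outside the range and is left out; MHC class II genes were higher in KR (0.80) and LR (0.63) and lower in KN1 (-0.57).

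In KN1 skin, where Notch1 was deleted from the basal layer, 325 genes changed: 142 rose and 183 fell, 77 and 48 by at least 2-fold. Gypc rose from 0.465 ± 0.351 CPM in 2 controls to 16.6 ± 3.54 CPM in 4 mutants (log2 fold change 4.95 ± 0.48, adjusted p = 0.000104). Counts on the estrogen receptor gene Esr1 rose from 5.29 ± 2.11 to 22.6 ± 5.38 CPM (2.06 ± 0.31, adjusted p = 0.00641). Whole-gene counts do not show whether these reads came from Esr1 itself or from the driver. Crispld2, which encodes a secreted protein, rose from 4.82 to 23.3 CPM (2.26 ± 0.41, adjusted p = 0.0135). Ceacam12 (1.97), Igsf3 (1.82), the adhesion receptor gene Adgrl3 (1.77) and the zinc finger gene Bnc2 (1.52) followed.

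Genes that fell in KN1 included Fmo2, a flavin monooxygenase, with a log2 fold change of -2.39 ± 0.56 (adjusted p = 0.0374), and Gsta2, a glutathione transferase, with -1.61 ± 0.36 (adjusted p = 0.03). The xenobiotic metabolism list did not pass (median -0.04, 1 of 21 fell, adjusted p = 0.473). Ctla2a fell with -1.91. The 4 other named genes that fell were mt-Co3, mt-Co2, mt-Nd3 and mt-Ts1 (-3.65 to -2.03), and mitochondrial counts were 1.17 ± 0.0869% in the KN1 controls and 0.79 ± 0.139% in the KN1 mice. The mitochondrial list was lower (median -1.08, 3 fell and 8 fell adjusted over the list alone, adjusted p = 7.7e-09, and adjusted p = 0.773 with an estimated correlation). Its mean log2 CPM was 7.27 and 7.55 in KN1 controls 1 and 7, merged and second-named, against 5.64 to 6.27 in KN1.

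In KN1, 2 of the immune lists were lower. The epidermal T cell list, which holds genes of the resident gamma-delta T cells, had a median of -0.57 with 23 of 24 negative (adjusted p = 9.29e-06, and adjusted p = 0.773 with an estimated correlation). The T cell receptor complex genes Cd3g (-1.41 ± 0.32, from 40.7 to 15.3 CPM), Cd3d (-1.29) and Trdc (-1.59, from 26.7 to 8.87 CPM) fell, and 4 fell adjusted over the list alone. Of the 16 alternatives, Cd3g was called in 7, Cd3d in 8 and Trdc in 7. Without KN1 control 1 the T cell median was -0.31 (adjusted p = 0.0248, and adjusted p = 0.982 with an estimated correlation). All 7 MHC class II genes were negative, with a median of -0.57 (adjusted p = 0.000873, and adjusted p = 0.773 with an estimated correlation). None of them fell over all genes and 3 fell adjusted over the list alone; Cd74 had -0.98 (adjusted p = 0.0748) and H2-DMb1 -0.61 (adjusted p = 0.0777). This fall of the MHC class II list rests on KN1 control 1: without that mouse the median was -0.21 (adjusted p = 0.569), and without KN1 control 7 it was -0.93. The Langerhans (adjusted p = 0.273), macrophage and neutrophil (0.31) and interferon (median 0.46, adjusted p = 0.132) lists did not pass.

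Lists of hair growth and of pigment cells were higher in KN1. The hair matrix list, genes of growing hair, had a median of 3.74 with 30 of 33 positive but no member called on either adjustment (adjusted p = 0.00226, and adjusted p = 0.813 with an estimated correlation). The median was the same with the 3 members at 0 counts in a group set to their bounds. Krt71, a keratin of the hair's inner root sheath in this list, was at 200 and 83.4 CPM in KN1 2 and 4. It was at 6.06 and 5.54 CPM in KN1 1 and 3, and at 0.459 and 0.217 CPM in KN1 controls 1 and 7. The melanocyte list was higher (median 1.13, adjusted p = 0.00954, and adjusted p = 0.773 with an estimated correlation), with Pmel up (1.01 ± 0.25, adjusted p = 0.0423) as the 1 gene called on either adjustment, and Dct at 1.26 (adjusted p = 0.169). The hedgehog and Wnt list was higher (median 0.34, adjusted p = 0.0373, and adjusted p = 0.773 with an estimated correlation). The hedgehog transducer Smo rose in it (0.73 ± 0.18), 2 rose adjusted over the list alone, and Gli1 had 1.37 (adjusted p = 0.156).

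The basal list was higher in KN1 (median 0.17, 16 of 19 positive, adjusted p = 0.0431, and adjusted p = 0.773 with an estimated correlation), with the hemidesmosomal integrin Itgb4 up (0.65, adjusted p = 0.0456) as the 1 gene called on either adjustment. Cholesterol synthesis was lower (median -0.38, 20 of 23 negative, 0 fell and 5 fell adjusted over the list alone, adjusted p = 0.000873, and adjusted p = 0.813 with an estimated correlation), with Ebp at -0.54 and Stard4 at -0.58. Sebocyte genes did not pass (median -0.16, adjusted p = 0.631). With the second-name covariate 19 genes were called, without the 3 second-named controls 41, and without KN1 control 7 alone 2. Leaving out KN1 2, 3 or 4 gave 120, 202 and 97 genes; Gypc was called in all 16 alternatives and Notch1 in 11. With the covariate the mitochondrial (median 0.07, adjusted p = 0.935), hair matrix (median 2.99, adjusted p = 0.184) and hedgehog and Wnt (median 0.35, adjusted p = 0.0775) lists did not pass, and the MHC class II list did (median -0.63, adjusted p = 0.00453, and adjusted p = 0.825 with an estimated correlation). With 1 mouse left out, cholesterol synthesis did not pass without KN1 control 7 (median -0.16, adjusted p = 0.697), nor the basal list without KN1 control 1 (0.01, adjusted p = 0.878) or KN1 3 (0.09, adjusted p = 0.123). The melanocyte median stayed at 1.06 without KN1 control 1 (adjusted p = 0.346) and 1.02 without KN1 2 (adjusted p = 0.0805). The hedgehog and Wnt list passed in 2 of 6 such fits, with medians from 0.21 to 0.58.

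With the 3 second-named controls left out, KN1 had 1 control, KN1 control 1. The Langerhans median was then -0.23, that of wound and stress 1.30 and that of cell cycle 0.30. Some lists passed in KN1 only with the covariate. Cell cycle was higher with it (0.43, adjusted p = 0.00963, and adjusted p = 0.915 with an estimated correlation). With the covariate the suprabasal list (-0.37, adjusted p = 0.0135, and adjusted p = 0.915 with an estimated correlation) and the dissociation response list (-0.69, adjusted p = 0.0135, and adjusted p = 0.825 with an estimated correlation) were lower.

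**Figure D3:**
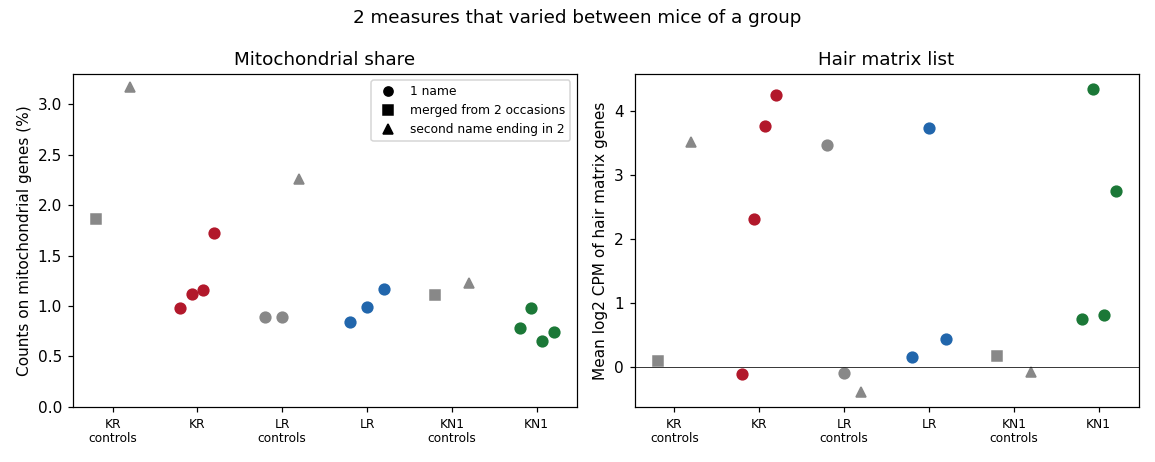
Share of counts on mitochondrial genes (left, percent) and mean log2 CPM of the 33 hair matrix genes (right) in each mouse; squares are the 2 libraries merged from 2 occasions, triangles the 3 second-named controls and circles all others. The mitochondrial share reached 3.17% in KR control 6, and hair matrix genes were high in mice of every mutant and in 2 of 7 controls.

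Changes were then compared between mutants. KR and LR shared 37 genes that rose and 7 that fell, where independent lists would share 1.00 and 0.37, with 0 changed in opposite directions. With the covariate KR and LR shared 8 that rose and 0 that fell, with the 3 second-named controls left out 7 and 0, and without KR control 6 2 and 0. KR and KN1 shared 11 that rose and 48 that fell (independent 0.989 and 1.65), of which 7 were mitochondrial or from a family of RP23-8J15 rows. LR and KN1 shared 10 and 6 (independent 1.24 and 0.454). All KR and KN1 controls are merged or second-named, and with the covariate these 2 mutants shared 3 genes that rose and 0 that fell, and with the 3 second-named controls left out 2 and 11. The comparisons use separate control mice but 1 estimate of the spread.

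Among the genes changed in all 3 mutants, named after their values were seen, 6 rose: Tslp, Mill1, Ceacam12, Ptprs, RP23-348B21.2 and RP24-138O17.3. Tslp (chromosome 18, 32815383 to 32819797, plus strand) rose by a log2 fold change of 5.58 ± 0.58 in KR, 2.58 ± 0.42 in LR and 2.19 ± 0.52 in KN1 (adjusted p = 0.000128, 0.00411 and 0.0378). Mill1, an MHC class I-like gene, rose by 1.46, 1.12 and 1.49, and Ceacam12, of an adhesion molecule family, by 2.20, 2.52 and 1.97. Cab39l, Ccdc152 and Vps41 fell in all 3, with Vps41 at -0.68, -0.59 and -0.57. Several of these calls hold weakly over the 16 alternatives of each comparison: Ptprs was called in 6 in KR, 4 in LR and 8 in KN1, Tslp in KN1 in 8, Ccdc152 in LR in 6 and Vps41 in KN1 in 7. Mill1 was called in 13, 14 and 13, and Ceacam12 in 14, 16 and 12.

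Tests of the differences between effects asked which genes responded differently to the deletions. By edgeR, 1 gene differed between KR and LR, 1 between LR and KN1 and 0 between KR and KN1, with 685, 1162 and 1251 genes at an unadjusted p under 0.05; DESeq2 called 4, 67 and 38. The 1 gene was Gypc (chromosome 18, 32528322 to 32560034, minus strand) each time, with log2 differences of 9.10 ± 0.93 between KR and LR (adjusted p = 0.000195) and -8.03 ± 0.90 between LR and KN1 (adjusted p = 0.000774). In LR, Gypc had 2 counts over 3 mice of 29897316 counts in all, and its lower level did not pass (adjusted p = 0.0714). The larger response of Tslp in KR than in LR and KN1 did not pass (differences of 2.99 and 3.39, adjusted p = 0.928 and 0.264). Ccl2 differed by 3.58 ± 0.71 between LR and KN1 (adjusted p = 0.122).

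The 3 control groups, which carry no deletion, differed in 4264 genes, so differences in level between cohorts were not tested. Levels of mice of several cohorts that stand side by side in the text and figures are descriptions of these mice.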

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

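The tests of a second sequencing occasion were chosen only after the covariate fits and the mitochondrial genes had been seen, and those of Gypc and Esr1 between drivers only after their values were seen.

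The effect on Gypc differed between mutants by a log2 difference of 9.10 between KR and LR and of -8.03 between LR and KN1. Among 82 sets of 4 mice examined for a mouse far from the rest, 2 were found, where chance gives about 1 in 20. Bnc2 was lowest in KN1 3 at 7.20 CPM, against 11 CPM in each of the others, with a gap of 0.993 of the range. Cab39l was highest in KR 4 at 51.3 CPM, against 40.5 to 40.9 CPM, with a gap of 0.956 of the range.

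The first pattern is the calls in KR and KN1, whose controls are all merged or second-named libraries. If these libraries differ from the rest for a reason other than the deletions, LR control 5 should lean the same way. It is the second-named control in a cohort with 2 ordinary controls. LR control 5 lay above the mean of LR controls 2 and 3 for 83.9% of the genes that fell in KR. This held for 81.4% of those that fell in KN1 and 50.5% of all tested genes. With control 2 or 3 in its place the shares were 15.4 to 36.1%. These give no separate background, since each control is set against the mean of the other 2. For genes that rose, LR control 5 lay below the mean of controls 2 and 3 for 58.3% in KR and 59.9% in KN1. That decides neither way, with 49.5% over all tested genes. The depth of the merged libraries is argued against, since with both thinned to 50% of their counts 248 and 318 genes were called in place of 264 and 325. For the 6 genes that rose in all 3 mutants nothing is decided: their median in LR was 2.11 against controls 2 and 3 alone and 2.03 against all 3, but 1 second-named control in 3 could hardly have moved it and the rises in KR and KN1 were not tested by it. A second sequencing occasion may thus underlie part or all of these falls. The lean was smaller than they were (a median log2 difference of 0.42 against a median fold change of -0.93 in KR and 0.26 against -0.75 in KN1). That sets no limit on the part, since the falls were chosen as calls, which enlarges their fold changes. LR control 5 was in neither contrast, so its lean was not enlarged in this way. LR control 5 is 1 mouse, the only one of its group with Xist counts above Ddx3y counts, and a real effect of the deletions stays open. Mitochondrial genes followed the library names. Their list mean log2 CPM was 7.27 to 8.75 in the merged and second-named controls of all 3 cohorts. It was 5.64 to 6.70 in the mutants and 5.90 in LR controls 2 and 3. The mitochondrial falls in KR and KN1 cannot be told apart from this difference between libraries.

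The second pattern is the rise of Gypc and Esr1 in both K14-CreERT mutants, whose driver names in the labels differ by a final 1 in KN1 and are taken here as the same. Esr1 rose by 1.77 ± 0.30 in KR and 2.06 ± 0.31 in KN1 and had 0.42 ± 0.29 in LR. Its counts were at 15.6 to 26.9 CPM in the KR and KN1 mice and at or below 7.63 CPM in all others. Whether these reads came from the gene itself or from the driver cannot be read from whole-gene counts. A difference between KR and LR passed for Gypc (edgeR quasi-likelihood test, adjusted p = 0.000195). For Esr1 it did not (unadjusted p = 0.0038, adjusted p = 0.98). A second sequencing occasion is argued against for Gypc, which had 6.60 ± 0.74 in KR with the covariate (adjusted p = 0.00162). A transgene effect on the neighbourhood may add to this, since 1 of 7 other tested genes within 500 kb was higher in both, but that gene is Tslp, which also rose in LR where Gypc did not. The K14-CreERT driver itself and deletion in the basal layer both remain possible for Gypc (adjusted p = 0.000195 between KR and LR) and were not told apart, and for Esr1 the difference between drivers is itself open; whether the controls carried the driver is not in the labels.

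For the 185 genes called in LR, 1 of the 10 splits of the 6 mice into 3 and 3 gave as many, the real one, and the highest of the others gave 5; 10 splits are too few for a share under 0.05.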

How the results depend on the processing

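The second-name and sex covariates, the omission of the 3 second-named controls and of LR control 5 from the KR and KN1 fits were chosen only after the data were seen. All 774 calls over the 3 comparisons, with shared genes counted in each, kept their sign with these. That was nearly given, since the calls were chosen from the same mice. The second-name covariate kept 11 of 264 calls in KR, 114 of 185 in LR and 13 of 325 in KN1, and the omission of the 3 controls kept 26, 100 and 29. The folds of the calls stayed closer to the first fit. With the covariate the median ratio was 0.753 in KR and 0.783 in KN1, and with the 3 controls left out 0.925 and 0.867. The loss of calls and these ratios do not decide whether the effects went away. The calls were chosen in the same data, and with the 3 controls left out 1 KR and 1 KN1 control stayed in. The sex covariate kept 264 calls in KR, 153 of 185 in LR and 321 in KN1. Xist counts lay above Ddx3y counts in 2 of 3 LR mice and 1 of 3 LR controls. In KR and in KN1 this held for 2 of 4 mutants and 1 of 2 controls. The omission of LR control 5 kept 264 calls in KR, 92 of 185 in LR and 325 in KN1. That mouse is in neither the KR nor the KN1 contrast. There its omission bears on the shared spread and hardly on the folds. Of 216 counts 121 stayed within 1.5 times. No paired analysis was possible because KR and KN1 share fewer than 2 replicate numbers with their controls. The LR numbers only name mice: deviations of same-numbered mice correlated at 0.07 and -0.08, and with the replicate block 137 genes were called. The 2 runs of merged mice were not fitted apart. Where calls changed, the cause was not tested.

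In KR (264), LR (185) and KN1 (325), DESeq2 called 1086, 547 and 820 genes; in LR 338 rose and 209 fell by DESeq2, against 144 and 41. Each cohort alone gave 672, 66 and 98, and all 7 controls pooled 809, 1052 and 1867. RLE factors gave 255, 182 and 348. The covariate gave 12 in KR and 19 in KN1, the sex covariate 531 in KR, and 3 controls left out 32 in KR and 41 in KN1. Without LR control 5, KR had 1353, LR 119 and KN1 640 genes. KR had 21 without KR control 4, 5 without KR control 6, and 65, 19, 651 and 24 without KR 1, 3, 4 and 5. LR had 70 without LR control 3 and 118, 246 and 60 without LR 1, 2 and 3. KN1 had 2 without KN1 control 7 and 120, 202 and 97 without KN1 2, 3 and 4.

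Lists called by camera (5 in KR, 9 in LR, 8 in KN1) were 0, 0 and 0 with an estimated correlation, and fry called 6 in KR, 0 in LR and 0 in KN1. In KR both methods called the MHC class II, Langerhans and mitochondrial lists. The suprabasal and the wound and stress lists did not pass by fry (adjusted p = 0.28 and 0.254). Basal genes, epithelial alarmins and type 2 immune genes, and macrophage and neutrophil genes passed by fry only (adjusted p = 0.0472, 0.0379 and 0.0472). Pooled controls gave 13 lists in KR and 3 in KN1. In KR the covariate and 3 controls left out each gave 10, leaving out KR control 6 gave 12 and KR 1 8. KN1 had 4 lists without KN1 control 1.

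Differences of effects (1 for KR and LR, 0 for KR and KN1, 1 for LR and KN1) numbered 4, 38 and 67 by DESeq2. For LR and KN1 there were 3 without a filter, 11 with the sex covariate and 21 with 3 controls left out, and 2, 13, 2 and 3 without LR control 2, LR control 5, LR 3 and KN1 4. For KR and LR there were 8 with 3 controls left out, 2 without LR control 2 and 8 without LR control 5, and for KR and KN1 3 without KR control 4.

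Genes changed alike (44 in KR and LR, 59 in KR and KN1, 16 in LR and KN1) numbered 207, 207 and 92 by DESeq2, 8, 3 and 3 with the covariate, and 7, 13 and 1 with 3 controls left out. In KR and LR they were 21 without LR control 3, 6 and 2 without KR controls 4 and 6, 21, 10, 74 and 13 without KR 1, 3, 4 and 5, and 24 without LR 3. In KR and KN1 they were 39 and 1 without KN1 controls 1 and 7, 8 and 4 without KR controls 4 and 6, 23, 8, 84 and 10 without KR 1, 3, 4 and 5, and 38, 24, 23 and 19 without KN1 1 to 4. In LR and KN1 they were 5 and 0 without KN1 controls 1 and 7, 10 and 8 without LR controls 2 and 3, 7 and 7 without LR 1 and 3, and 9, 6 and 5 without KN1 2, 3 and 4. Control cohorts differed in 4264 genes, 1364 with 3 controls left out, 1883 without KN1 control 7 and 5158 without LR control 5.

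Signs turned with pooled controls for Thbs1 in KR (-0.17), Notch1 in LR (0.21), and Ebp (0.16) and H2-DMb1 (0.0839) in KN1. Notch1 in LR, uncalled, had 0.0204 without LR control 5, 0.0328 without LR 2 and 0.0175 with 3 controls left out, and ran from -0.105 without LR control 2. Lrig1 in LR had -0.0325 without LR 3 and 0.515 without LR 2, and Rbpj in KN1 had 0.0913 with the covariate.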

Other observations

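The tests of lists between mutants and of the hair matrix genes were chosen only after the data were seen. As a list, MHC class II genes differed between KR and KN1 by a median log2 difference of 1.49 (camera adjusted p = 1.18e-16, and adjusted p = 0.0443 with an estimated correlation), and Langerhans genes by 1.09 (adjusted p = 1.59e-07, and adjusted p = 0.0443 with an estimated correlation). The list of epithelial alarmins and type 2 immune genes, which holds Tslp, differed by 0.50 (adjusted p = 0.00199, and adjusted p = 0.0443 with an estimated correlation). With 1 of the 12 mice left out, all 3 differences passed in 12 of 12 fits with the preset; with an estimated correlation the first 2 passed in 3 of 12 and the alarmins in 2 of 12. The MHC class II difference was 1.06 without KN1 control 1 (adjusted p = 0.126 with an estimated correlation) and 1.00 without KR control 6 (adjusted p = 0.149 with an estimated correlation). The MHC class II difference between LR and KN1 was 1.24 (adjusted p = 1.74e-13, and adjusted p = 0.189 with an estimated correlation). Other immune lists also differed between KR and KN1 by camera with the preset. Epidermal T cell genes differed by 0.75 (adjusted p = 9.92e-06) and macrophage and neutrophil genes by 1.17 (adjusted p = 0.00162). Interferon genes went the other way, by -0.62 (adjusted p = 0.0352). With an estimated correlation these had adjusted p = 0.307, 0.0967 and 0.803. Sebocyte genes differed between KR and LR, the mutants that both lost Rbpj, by 1.06 (adjusted p = 1.39e-07, and adjusted p = 0.472 with an estimated correlation). Within KR the sebocyte mean log2 CPM was 6.12 and 6.21 in KR 3 and KR 5, and 4.69 and 5.12 in KR 1 and KR 4. KR 3 and KR 5 are the KR mice with Xist counts above Ddx3y counts. Other groups went both ways by these counts. LR control 5, with Xist above, had 4.81 against 5.19 and 5.16 in LR controls 2 and 3. KN1 1 and 2 had 4.89 and 5.04 against 4.85 and 5.11 in KN1 3 and 4. Means were higher with Xist above in LR 2 and 3 (5.00 and 4.65, against 4.37 in LR 1). The same held for KR control 4 (5.38 against 5.04) and KN1 control 1 (5.18 against 4.75).

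Pyy, which is among the named genes only in KR, also rose in LR by 2.58 ± 0.46 (adjusted p = 0.0117) and had 1.73 ± 0.50 in KN1 (adjusted p = 0.0881). Meox1, chosen after its value was seen, had 87 counts in the LR mice and 0 in their controls, at least 26.4-fold higher. Trdc was at 29.8 and 23.5 CPM in the KN1 controls and 24.4 CPM in LR control 5, and at or below 12.2 CPM in every other mouse.

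The third pattern is the hair matrix list, called higher in KN1; its test was chosen after the result was seen and replaced an earlier version, run and then dropped because it left out KN1 mice picked by their own level. Krt71 was above 10 CPM in 8 mice (36.9 to 200 CPM) and at or below 6.06 CPM in the other 10, and the 8 were 3 KR, 1 LR, 2 KN1 and 2 control mice. The list's mean log2 CPM lay above the median of the KN1 mice (1.78) in 2 of 7 control mice, KR control 6 and LR control 2, with no deletion. Its call in KN1 remained when any 1 of the 6 mice was left out (adjusted p from 0.000195 to 0.036, and adjusted p = 0.782 to 0.982 with an estimated correlation), with a median from 2.08 without KN1 2 to 4.77 without KN1 control 1. KN1 1 and 3 were below the Krt71 cutoff but above both KN1 controls, at 6.06 and 5.54 CPM against 0.459 and 0.217 CPM. Their list means were 0.749 and 0.808, against 0.163 and -0.0804 in KN1 controls 1 and 7. Patches of growing hair in single mice of skin described as resting may account for part of the list's call in KN1. Neither of the 2 KN1 controls was high, and an effect of Notch1 loss on the hair cycle stays open with 2 controls.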
